A study of Mus musculus with 12 samples.

How the data were processed

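Long noncoding RNAs (lncRNAs) were measured by sequencing of polyadenylated RNA from livers of CD-1 mice, an outbred stock, at 8 weeks of age. The mice had received TCPOBOP, an agonist of the nuclear receptor CAR, or PCN, an agonist of the nuclear receptor PXR. Livers were taken 3 h after injection (11 AM) or 6 h after injection (2 PM). Each library held RNA pooled from 2 to 6 livers, taken from whole tissue or from purified nuclei, and was prepared with or without retention of the strand. The 12 libraries formed 8 groups, and 2 of the groups, TCPOBOP-treated nuclear RNA at 3 h from females and from males, held 3 pools each. The other 6 groups were 1 library each. Vehicle-treated libraries belong to another series and were not used here, so no treatment was compared with vehicle.

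The authors deposited 1 table of 15558 lncRNAs with RPKM values (reads per kilobase of transcript and per M reads, where M is 1e6), per the file headers, on a sheet whose name says FPKM. Reads had been aligned with TopHat2 to mouse genome build mm9, per the submitters' processing notes. The version of the aligner, the counting tool, its strand setting and the annotation source are not given in the sources used here. Each lncRNA carries mm9 coordinates, a strand and a class in its identifier: 13343 were intergenic, 1966 antisense to a gene and 249 intragenic. The strand was not given for 184 of them. The table pairs no identifier with a gene symbol, and the 151 symbols of 10 gene lists fixed in advance (nuclear-retained, snoRNA-host, X-inactivation, imprinted, microRNA-host, non-parenchymal, stress and growth lncRNAs, CAR and PXR targets, sex-biased genes and clock genes) matched 0 entries. Markers of other liver cell types were among them and could not be read. The reference annotation supplied was of build GRCm38, so no coordinate was converted and loci are given by their mm9 positions. Of 25 value columns, 12 matched the labels of a library and were used, and 13 were not used here.

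The RPKM values stepped in whole reads. A read total per library and a length per lncRNA were recovered for which 100% of the 89242 values above 0 were whole numbers of reads, within 1e-06 of a read. The length equalled the full span for 9844 of 12497 lncRNAs above 0 in any library. Recovered reads give the depth behind each value, and a count of 0 allows up to 3 reads. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

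Groups were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.1), with a mean-variance trend and Benjamini-Hochberg adjustment, and a call was an adjusted p under 0.05. Fold changes are on that scale, which understates changes of low lncRNAs. The sex comparison used the 6 replicated pools and lncRNAs with an RPKM of at least 0.1 in 3 of them. The agonist and time effects in whole-tissue RNA came from 1 additive fit of the 4 stranded libraries, with 1 residual degree of freedom and an RPKM of at least 0.1 in 2 libraries. The comparisons of nuclear TCPOBOP libraries with 1 nuclear PCN library and with 1 whole-tissue library were contrasts in a fit of the 8 unstranded libraries, with 4 residual degrees of freedom. There the single library was assumed to vary like the replicated pools. Comparisons of 1 library with 1 library have no replicate check and no test, and used lncRNAs with an RPKM of at least 0.5 in either library. In the sex and nuclear fits the p-values rest on the spread between the replicated pools, each of several livers. A lncRNA with 0 reads in every replicated pool has no spread there. In the nuclear contrasts its error comes from the mean-variance trend alone. In the additive fit of 4 single libraries the error term is the agonist-by-time interaction, so its p-values measure no spread between pools.

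Annotation classes, chromosomes X and Y and lncRNAs without a given strand were tested as lists with camera (preset correlation of 0.01, and again with an estimated correlation) and fry. For single libraries, the median of a list was ranked among 10000 random lists of the same size matched on mean expression. Neighbouring calls in 1 direction no more than 50000 bases apart were joined into regions of 3 or more lncRNAs, a rule chosen after the calls had been seen. No-effect values for contrasts that share libraries were added after the results were seen and came from 200 simulations with normal noise of equal size in each library, with calls ranked by difference or by difference over a spread with 4 degrees of freedom. Sums over a region hold its called lncRNAs alone, so they describe the calls and are not a test of the region. The named lncRNAs were the 12 highest and 12 lowest by fold change among calls whose libraries did not overlap between the sexes, with a mean RPKM of at least 0.5 on the higher side. For the other comparisons there were 5 and 5, going the same way at both times or with both agonists where these apply. Groups, tests, gene lists, that rule and most alternatives were fixed before the data were examined. At most 2 identifiers in each direction are printed per comparison, and other loci are given by position.

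Each model was first tested on simulated reads drawn at the recovered means and read totals, with 200 lncRNAs changed by known folds. In the sex design over 5951 lncRNAs, 14% of 2-fold, 40% of 4-fold, 76% of 8-fold and 88% of 16-fold changes were called, and 8.40% of calls were false. In the agonist design over 2270 lncRNAs, 2% of 2-fold, 44% of 4-fold, 58% of 8-fold and 64% of 16-fold changes were called. All dispersions came from the replicated nuclear pools, and each simulated agonist effect was the same at both times. The stranded libraries have no replicates, so these shares may not hold for them. With 1 library on a side, over 7401 lncRNAs, 38% of 16-fold changes were called in the nuclear agonist contrast and 28% in the contrast of nuclear with whole-tissue RNA. The planned design named the values FPKM, and the same tests were applied to the RPKM values.

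Read totals were 25.2 to 27.8 M in the 4 stranded libraries and 40.3 M in the unstranded whole-tissue library. They were 21.9 M in the nuclear PCN library, 22.9 to 32.0 M in the female pools and 7.31 to 11.9 M in the male pools. A floor of 3 reads over 1000 bases corresponded to 0.0745 RPKM in the deepest library and 0.410 RPKM in the shallowest. No libraries of a group matched within sampling noise: the chi-square per lncRNA between replicate pools, near 1 for sampling alone, was 5.33 to 12.8.

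Alternatives were other pseudocounts (0.01 and 1), no filter and a mean RPKM of at least 1, equal medians, quantile normalization, no variance trend, a 2-fold minimum and the pool number as a block. Further ones were leaving out each pool, spread from all 8 or all 12 libraries, limma-voom on the recovered reads, and the fit without chromosomes X and Y. A test of the agonist-by-time difference with spread from the 12 libraries was tried and left out, because lncRNAs at 0 in every replicated pool gave no usable spread. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.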

Results

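lncRNA expression was profiled in livers of CD-1 mice given TCPOBOP or PCN. Whole-tissue RNA of males was sequenced with strand information at 3 h and 6 h after each agonist, 1 library of 6 livers each. A further whole-tissue library from TCPOBOP-treated males at 3 h was made without strand, as were all nuclear libraries: 3 female and 3 male TCPOBOP pools and 1 male PCN library of 2 livers, all at 3 h. lncRNAs took 0.795% to 0.918% of reads in the stranded libraries and 3.79% to 5.11% in the unstranded ones. Between 5619 and 6223 lncRNAs were above 0 in a stranded library, and between 6692 and 9244 in an unstranded one. The 3 female pools were the experiment coded G86, the 3 male nuclear TCPOBOP pools G95, and the other 6 libraries G81.

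The first comparison asked which lncRNAs differ between female and male liver nuclei 3 h after TCPOBOP. At chromosome X 100655410-100678927, ncRNA_inter_chrX_15394 had 349 ± 30.9 RPKM in female pools (SD, n = 3) and 0.134 ± 0.0319 in male pools (SD, n = 3), a log2 difference of 10.55 (SE 0.16). At chromosome 5 146227188-146669283, 16 intragenic and antisense lncRNAs summed to 347 ± 43.9 RPKM in females and 5.87 ± 9.64 in males. In the opposite direction, 9 intergenic lncRNAs at chromosome 8 47968284-48060026 summed to 0.191 ± 0.0878 RPKM in females and 5.77 ± 0.988 in males. Of 5951 lncRNAs tested with limma, 523 passed at an adjusted p under 0.05, 233 higher in females and 290 higher in males. At least 4-fold differences were found for 92 of the former and 69 of the latter, and at least 16-fold ones for 24 and 4.

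Many female-higher calls had no reads in male nuclei. None was found in any male pool for 66 of the 233, against 20 of the 290 male-higher calls without a read in any female pool. The male pools held 29.9 M reads together and the female pools 79.8 M, so a count of 0 is easier to reach in males and the counts do not compare the sexes. ncRNA_intra_chr7_5919, at chromosome 7 14253224-14384718, had 35.7 ± 6.51 RPKM in females and 0 reads in males, at least 53.7-fold higher against a floor of 3 reads over the male pools. Its neighbour at chromosome 7 14385459-14499841 had 16.2 ± 4.04 RPKM in females and 0 reads in males, at least 100.5-fold higher by the same floor. Another 9 of the 12 highest calls lay in the chromosome 5 region. One of these, at chromosome 5 146228595-146406959, had 34.7 ± 12.3 RPKM in females and 0 reads in males, at least 56.3-fold higher. Another, at chromosome 5 146393193-146600990, had 70.9 ± 17.6 RPKM in females and 0.954 ± 1.44 in males. The call at chromosome 5 146340359-146612450 (52.6 ± 10.5 against 1.43 ± 2.48 RPKM) was lost without any 1 of the female pools and in 2 other fits, and its adjusted p in limma ranged from 2.25e-06 to 0.0761 over all fits.

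Female-higher calls formed 11 regions with 61 lncRNAs. After the chromosome 5 region came chromosome 8 95577587-95676870, with 10 lncRNAs summing to 667 ± 131 RPKM in females and 316 ± 36.5 in males, and chromosome 15 60696171-60756184, with 10 intergenic lncRNAs summing to 16.4 ± 2.97 and 0.0571 ± 0.0647 RPKM. The sum at chromosome 3 7613844-7648437 was 3.21 ± 1.22 RPKM in females and 0.120 ± 0.104 in males. In the chromosome 5 and 8 regions lncRNAs overlap one another and annotated genes, and in libraries without strand their reads cannot be told from those of an overlapping gene or a near-identical copy.

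Male-higher calls formed 14 regions with 54 lncRNAs. ncRNA_inter_chrX_15435, at chromosome X 120395211-120395614, had 2.29 ± 0.259 RPKM in males and 0 reads in females, at least 24.6-fold higher in males against a floor of 3 reads over the female pools. It lay in a region at chromosome X 120382071-120834550 whose 4 lncRNAs summed to 5.03 ± 0.726 RPKM in males with 0 in females, and to 39.7 and 13.6 RPKM in the male unstranded whole-tissue and nuclear PCN libraries. ncRNA_inter_chr4_3468, at chromosome 4 103055088-103169173, had 3.42 ± 0.478 RPKM in males and 0.0871 ± 0.0574 in females. At chromosome 4 115036425-115146962 an antisense lncRNA had 1.70 ± 0.803 RPKM in males and 0 reads in females, at least 125-fold higher. The 4 called lncRNAs at chromosome 8 116533748-116679361 summed to 57.1 ± 3.81 RPKM in males and 15.7 ± 4.37 in females. Calls among the 12 highest in males at chromosome 7 16372414-16372731 and chromosome X 122647432-122647634 were lost without any 1 of the female pools.

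**Figure D1:**
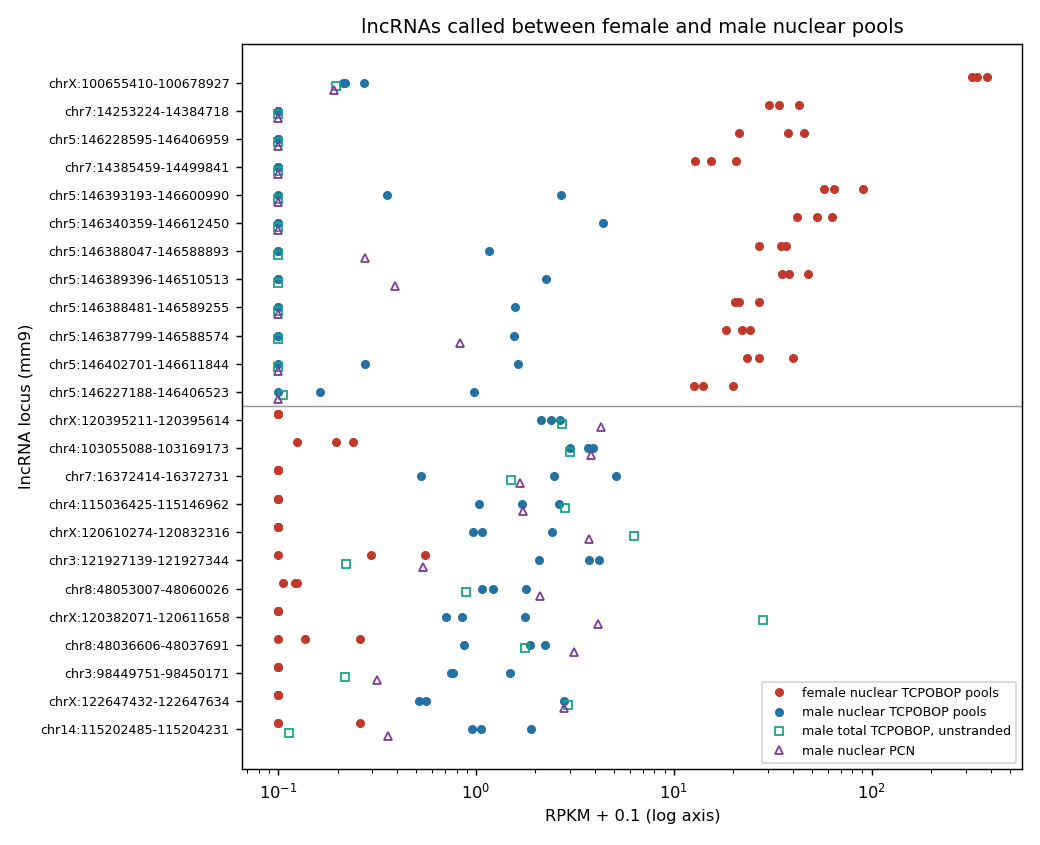
RPKM + 0.1 on a log axis for the 12 lncRNAs highest in females (above the line) and the 12 highest in males (below it), 1 filled point per nuclear TCPOBOP pool and open symbols for the other male unstranded libraries. At chromosome X 100655410-100678927 the female pools average 349 RPKM and the male pools 0.134 RPKM.

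By class, 160 intergenic lncRNAs were higher in females and 219 in males of 4594 tested, 51 and 64 of 1214 antisense, and 22 and 7 of 143 intragenic. Of the 22 intragenic ones, 9 lay in the chromosome 5 region and 3 in the chromosome 8 region at 95577587-95676870, where lncRNAs overlap. Adjusted over the list alone, 371 intergenic, 122 antisense and 41 intragenic lncRNAs passed. Intragenic lncRNAs stood higher in females than other lncRNAs (median log2 0.10, camera adjusted p = 0.00472), but not at an adjusted p = 0.161 with an estimated correlation. lncRNAs without a given strand did too (7 higher, 1 lower, 79 not passing of 87, adjusted p = 0.00436, or adjusted p = 0.0530 with an estimated correlation). Of 110 chromosome X lncRNAs 4 were higher in females and 8 in males, 14 adjusted over the list alone. They did not stand apart from the rest (camera adjusted p = 0.964). The fry mixed adjusted p was 1e-09 for chromosome X and at most 6.44e-06 for every tested list, so it is not particular to this chromosome. No chromosome had an excess of calls after adjustment over chromosomes and directions. The lowest adjusted p, by Fisher's exact test, was 0.0608 for female-higher calls on chromosome 5, where 26 of 351 were called. No chromosome Y lncRNA met the filter.

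The values of 1860 lncRNAs (31.3% of those tested) did not overlap between the sexes, where chance gives 10%, and 1524 had an unadjusted p under 0.05. Each sex came from 1 experiment, so sex and experiment cannot be told apart and no value within an experiment can be given. In both other male unstranded libraries, which are of experiment G81, 12 of the 12 named female-higher loci and 9 of the 12 named male-higher loci lay nearer the male than the female mean. These are the most extreme calls: over all calls both libraries lay nearer the male mean for 64.8% of the female-higher and 24.5% of the male-higher ones. These shares depend on the scaling: they were 58.4% and 36.2% with equal medians and 57.9% and 41.0% with quantile normalization. The count of calls was 205 without female pool 1, 232 without female pool 3, 279 without female pool 2 and 334 without male pool 1. With the medians of the libraries set equal 58.5% of calls were higher in females, against 44.6%, because the median difference moved from -0.09 to 0.05. limma-voom on recovered reads called 778, 31.6% of them higher in females.

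The second comparison set TCPOBOP against PCN in stranded whole-tissue RNA of males. ncRNA_as_chr10_8460, at chromosome 10 7498997-7502517, had 17.1 RPKM (1544 reads) with TCPOBOP and 1.14 (103 reads) with PCN at 3 h, and 22.8 (2231 reads) and 2.08 (184 reads) at 6 h, ratios of 15 and 11. At chromosome 7 26670803-26677472 an intergenic lncRNA had 1.60 and 2.01 RPKM with TCPOBOP and 0.216 and 0.351 with PCN. ncRNA_inter_chr11_9914, at chromosome 11 79804087-79805822, had 66 and 140 reads with TCPOBOP at 3 h and 6 h and 0 with PCN at either time. It was not seen in every TCPOBOP library: the unstranded whole-tissue library had 0 reads, the male nuclear pools 1, 0 and 0, and the female pools 99, 1 and 0. The other way, an intragenic lncRNA at chromosome 5 146389075-146670818 had 124 and 97.2 RPKM with PCN and 48.7 and 39.6 with TCPOBOP. The chromosome 7 and chromosome 5 loci fall outside the naming rule and were chosen after their values were seen.

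limma called 0 of 2270 lncRNAs, with the lowest adjusted p at 0.591 and 162 at an unadjusted p under 0.05. With a mean RPKM of at least 1 it called 17 of 251, 10 higher with TCPOBOP and 7 higher with PCN. With spread taken from all 12 libraries it called 396, of which 326 were at 0 in all 6 replicated pools and had no spread there, while 45 had a mean of at least 0.1 RPKM in those pools. The 3 higher loci that the rule names first (log2 4.44, 3.99 and 3.59) were among the 17. For the chromosome 10 locus the adjusted p in limma moved from 0.591 to 7.9e-23 in the same 4 libraries. These calls thus depend on which lncRNAs enter the fit. The 5 lower loci named had log2 differences from -2.18 to -1.49 and adjusted p from 0.596 to 0.687 in limma. ncRNA_inter_chr8_6870, at chromosome 8 34301441-34301788, had 4 reads at 3 h and 0 at 6 h with TCPOBOP, and 9 and 8 with PCN. ncRNA_inter_chr5_4750, at chromosome 5 146879751-146881080, had 2 and 7 reads with TCPOBOP and 26 and 25 with PCN.

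At 3 h alone 23 of 633 lncRNAs were at least 4-fold apart, 13 higher with TCPOBOP, and at 6 h 23 of 566, 14 higher with TCPOBOP. At both times 5 were at least 4-fold higher with TCPOBOP and 0 at least 4-fold higher with PCN, against a mean of 0.922 and a maximum of 4 in 1000 shuffles of lncRNAs between the times. The count of 5 depends on the pseudocount of 0.1: it was 11 with a pseudocount of 0.01 and 1 with a pseudocount of 1. The shuffles also moved each lncRNA on its own, though 2 of the 5 overlap, so their maximum takes no account of linked lncRNAs. The 5 are the loci on chromosomes 10, 11 and 7 above and 2 overlapping intragenic lncRNAs at chromosome 19 40074047-40170291 and 40083334-40185159. The first of these had 2.75 and 2.54 RPKM with TCPOBOP and 0.550 and 0.469 with PCN, and the second 4.16 and 1.73 RPKM with TCPOBOP and 0.208 and 0 with PCN. At 2-fold, 15 were higher and 8 lower at both times. Antisense lncRNAs (camera adjusted p = 0.581) and the other classes, chromosome X and the lncRNAs without a given strand did not stand apart in limma, at the same adjusted p. For antisense lncRNAs the fry mixed adjusted p was 0.0207, but none of the 458 passed and limma had 1 residual degree of freedom.

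**Figure D2:**
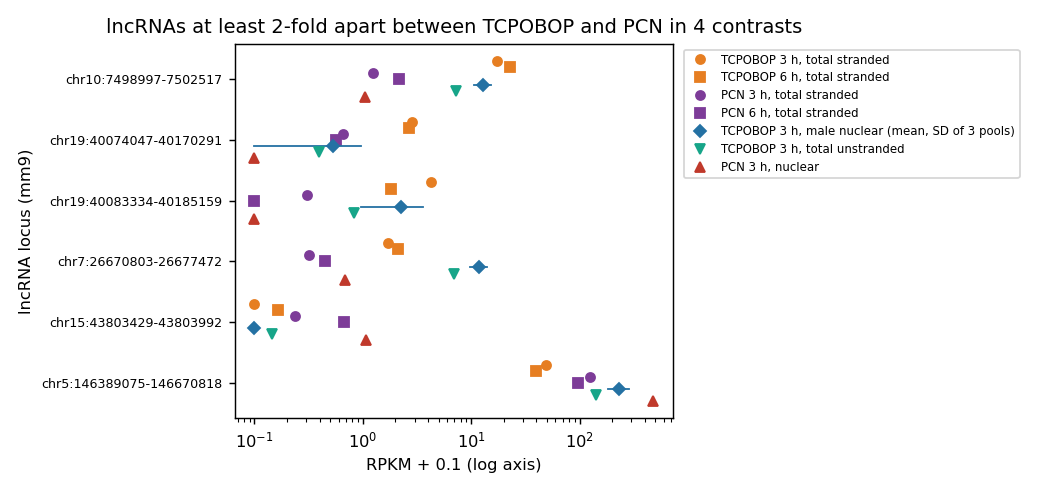
RPKM + 0.1 on a log axis for the 6 lncRNAs at least 2-fold apart between TCPOBOP and PCN, in 1 direction, in 4 contrasts: stranded whole tissue at 3 h and 6 h, nuclear RNA, and the unstranded G81 pair. Diamonds give the mean of 3 male nuclear pools with the SD as a bar and other symbols are single libraries, with 17.1 and 1.14 RPKM at 3 h at chromosome 10 7498997-7502517.

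The third comparison set 6 h against 3 h in the same 4 libraries, where time after injection and clock hour go together. An intergenic lncRNA at chromosome 8 36467573-36478552, ncRNA_inter_chr8_6896, went from 6.26 RPKM at 3 h to 0.700 at 6 h with TCPOBOP and from 3.02 to 0.187 with PCN, over 1642, 199, 793 and 48 reads. Its log2 difference was -3.22 (SE 0.24). The locus was all but absent from the unstranded libraries, which are all of 3 h. It had 0.0024 RPKM in whole tissue with TCPOBOP and 0 in the nuclear PCN library. The nuclear TCPOBOP pools had 0.0027 ± 0.0048 RPKM in males and 0.0072 ± 0.0124 in females. Next to one another on chromosome 10, 3 intergenic lncRNAs between 121862309 and 121865778 had 0.748 to 0.822 RPKM with TCPOBOP and 0.328 to 0.411 with PCN at 3 h, and 0 reads with either agonist at 6 h. Higher at 6 h was ncRNA_inter_chr5_4321, at chromosome 5 82334927-82355072, with 0 and 0.0431 RPKM at 3 h and 0.557 and 0.572 at 6 h. With both agonists, 2 lncRNAs were at least 4-fold higher and 6 at least 4-fold lower at 6 h.

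limma called 0 of 2270, with the lowest adjusted p at 0.328, which held for the chromosome 8 locus too, and 273 at an unadjusted p under 0.05. The median log2 difference was -0.16. With a mean RPKM of at least 1, 27 of 251 were called, 7 higher and 20 lower at 6 h. The chromosome 8 locus was among them, at an adjusted p = 8.0e-17 in limma, so its call depends on which lncRNAs enter the fit. With spread from all 12 libraries 469 were called, 336 of them at 0 in all 6 replicated pools. The lists had camera adjusted p from 0.844 to 0.971 in limma. The fry mixed adjusted p was 0.0330 for chromosome X and intergenic lncRNAs, of which none passed, with 1 residual degree of freedom.

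In nuclear RNA, the agonist comparison set TCPOBOP (3 male pools) against PCN (1 male library) at 3 h. Antisense and intragenic lncRNAs in a few stretches were higher with TCPOBOP. At chromosome 12 104971050-105142526, 11 of them summed to 85.3 ± 25.7 RPKM with TCPOBOP (SD, n = 3) and 4.21 with PCN. At chromosome 19 40083308-40187923, 4 intragenic lncRNAs summed to 264 ± 42.7 RPKM and 16.5 RPKM, and at chromosome 8 95583784-95675109, 9 summed to 298 ± 8.51 and 41.1 RPKM. In whole-tissue unstranded TCPOBOP RNA, from the experiment of the PCN library, these regions summed to 9.32, 146 and 13.3 RPKM. Of 7401 lncRNAs limma called 316, 212 higher and 104 lower with TCPOBOP: 93 and 4 antisense, 97 and 94 intergenic, 22 and 6 intragenic.

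Among named loci, ncRNA_as_chr12_10861 at chromosome 12 105009689-105141254 had 16.4 ± 3.53 RPKM with TCPOBOP and 0.225 (1 read) with PCN, a log2 difference of 5.64 (SE 0.52, limma adjusted p = 0.00749). ncRNA_intra_chr12_10863, at chromosome 12 105010932-105101174, had 6.06 ± 3.75 RPKM and 0 reads, and its call was lost with a pseudocount of 1, without male pool 1 and without male pool 3 (adjusted p from 0.00555 to 0.0981 over all fits in limma). Lower with TCPOBOP were ncRNA_inter_chrX_15443 at chromosome X 121868146-121987095, with 0 reads in the 3 pools and 9.94 RPKM (46 reads) with PCN, and ncRNA_inter_chr1_211 at chromosome 1 55185423-55185650, with 0 reads and 7.40 RPKM (37 reads). In the whole-tissue TCPOBOP library of G81 they had 0.588 RPKM (5 reads) and 9.14 RPKM (84 reads), so the chromosome 1 locus was not lower with TCPOBOP there. The lower calls include chromosome Y lncRNAs with 0 reads in all 6 replicated pools, which have no spread between pools. Agonist and experiment cannot be told apart here. Of the 316 calls 162 (51.3%) had the same sign between the TCPOBOP and PCN unstranded libraries of experiment G81, which differ in compartment too: 118 of 191 intergenic (61.8%) and 31 of 97 antisense calls (32.0%). That pair shares the PCN library with this contrast, which alone gives the same sign for 90.5% of calls in simulations with no effect (lowest 86.1%) when ranked by difference over spread and for 96.5% (lowest 94.0%) when ranked by difference. The observed 51.3% lies below both, and what lowers the share was not tested. With medians equal 48.7% of calls were higher with TCPOBOP, against 67.1%, as the median difference moved from 0.25 to 0.00, and calls numbered 86 without male pool 1 and 119 without male pool 3.

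A further comparison set the same male nuclear pools against 1 unstranded whole-tissue library, both after TCPOBOP at 3 h. At chromosome 8 95583784-95676870, 19 antisense and intragenic lncRNAs summed to 815 ± 62.7 RPKM in nuclei and 127 RPKM in whole tissue. ncRNA_intra_chr8_7322, within it at 95634042-95667133, had 32.2 ± 4.33 against 0.768 RPKM (log2 5.21, SE 0.36, limma adjusted p = 0.00253). ncRNA_as_chr1_605, at chromosome 1 141508535-141803218, had 7.60 ± 2.25 against 0.108 RPKM. Lower in nuclei were 7 lncRNAs at chromosome X 120120394-121301038, which summed to 3.82 ± 1.21 RPKM in nuclei and 46.2 in whole tissue, with 14.2 in the nuclear PCN library. ncRNA_inter_chr1_211 had 0 reads in the 3 nuclear pools and 9.14 RPKM in whole tissue, and ncRNA_intra_chr11_9610 (chromosome 11 33654764-33855712) 0 reads and 7.08 RPKM. The nuclear PCN library of G81 had 7.40 RPKM (37 reads) and 5.68 RPKM (38 reads) for these, so they were present in nuclei of that experiment. For the higher loci on chromosomes 8 and 1 it had 4.93 and 0.372 RPKM.

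limma called 764 of 7401, 537 higher and 227 lower in nuclei: 305 and 23 antisense, 202 and 197 intergenic, 30 and 7 intragenic. Here too the lower calls include chromosome Y lncRNAs with 0 reads in every replicated pool. Compartment and experiment cannot be told apart here. Between the nuclear PCN and whole-tissue TCPOBOP libraries of G81, which differ in agonist, 651 of the 764 (85.2%) had the same sign. That pair shares the whole-tissue library with this contrast, and the 85.2% lies below what the shared library alone gives in simulations with no effect, 89.2% (lowest 85.7%) ranked by difference over spread and 93.7% (lowest 91.5%) ranked by difference. With medians equal 56.0% of calls were higher in nuclei, against 70.3%, as the median difference moved from 0.27 to 0.03, and calls numbered 415 without male pool 1 and 485 without male pool 3. This comparison and the one before it share the 3 male pools: 246 calls were common to both, all of the same sign. In simulations with no effect the shared pools alone gave a mean of 48.2 (highest 60) common calls ranked by difference, 92.8% of the same sign, and 121.5 (highest 149) ranked by difference over spread, 77.0% of the same sign. Their fold changes correlated across lncRNAs at 0.751, against 0.249 in simulations with no effect, with a covariance of 0.840 against 0.143. The simulated values hold independent noise in each library and no offset common to the 3 male pools. They leave out an effect of the experiment of those pools, so exceeding them does not tell compartment or agonist from experiment. Each set of calls holds 4 of the 5 tested chromosome Y lncRNAs, lower in the nuclear TCPOBOP pools.

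The next comparisons set 1 library against 1 and have no replicate check. After PCN at 3 h, nuclear unstranded RNA stood above whole-tissue stranded RNA by a median log2 ratio of 2.32 over 1893 lncRNAs. The ratio was 3.02 for antisense, 2.05 for intergenic and 0.98 for intragenic lncRNAs, at percentiles 100, 0 and 0 of matched random lists. Higher in nuclei was ncRNA_as_chr12_10887 at chromosome 12 105583272-105651568, with 270 RPKM (1400 reads) against 0 reads. Lower was ncRNA_intra_chr16_13383 at chromosome 16 57391224-57391795, with 0 reads against 295 RPKM (4333 reads). In whole-tissue RNA after TCPOBOP at 3 h, the unstranded library stood above the stranded one by 2.24 over 1933 lncRNAs: 2.83 for antisense, 2.06 for intergenic and 0.74 for intragenic, at percentiles 100, 0.05 and 0. The same chromosome 12 and 16 loci stood apart in the same directions, at 87.9 RPKM against 0 reads and 0 reads against 301 RPKM. Between the unstranded whole-tissue and nuclear libraries of G81 the median log2 ratio was -0.06 over 2075 lncRNAs, with r = 0.802 across lncRNAs.

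**Figure D3:**
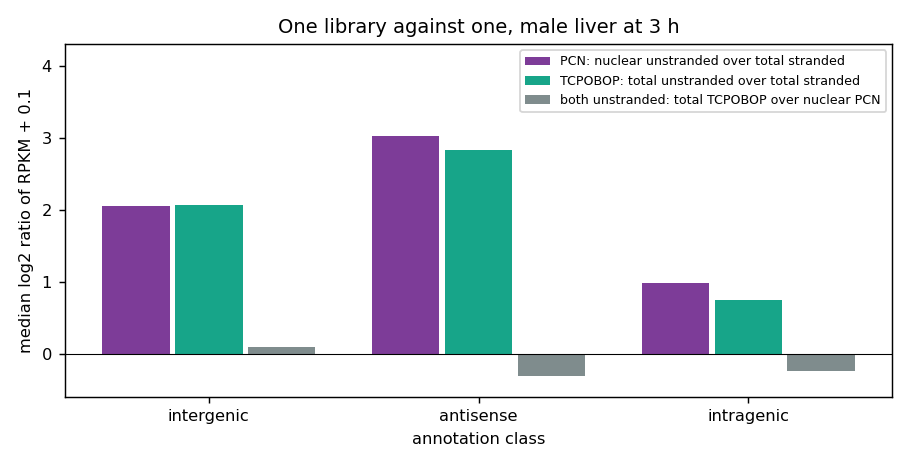
Bars give the median log2 ratio of RPKM + 0.1 between single male libraries at 3 h, by annotation class. Antisense lncRNAs have the highest medians in both contrasts with a stranded library, 3.02 and 2.83, and a median of -0.31 between the unstranded libraries.

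The agonist difference was compared between whole-tissue and nuclear RNA, whose fits share no library. Over 1769 lncRNAs tested in both, log2 differences correlated across lncRNAs at r = 0.162 (Spearman 0.181), and lncRNAs are not independent replicates. Of 150 lncRNAs called in nuclear RNA 103 (68.7%) had the same sign in whole-tissue RNA (exact binomial test, two-sided, p = 5.6e-06). With a mean RPKM of at least 1 in both, r was 0.314 over 161 lncRNAs and 23 of 31 calls had the same sign (exact binomial test, two-sided, p = 0.0107). Both tests take lncRNAs as independent trials, but the nuclear calls hold runs of overlapping lncRNAs, so these p-values are not reliable. All PCN libraries come from experiment G81, so an effect of the PCN mice alone may contribute to the shared signs. The chromosome 10 locus stood at 12.8 ± 2.35 RPKM in male nuclei with TCPOBOP and 0.945 with PCN, and the chromosome 7 locus at 26670803-26677472 at 11.8 ± 2.22 and 0.588. The PCN-higher lncRNA at chromosome 5 146389075-146670818 stood at 233 ± 51.4 RPKM with TCPOBOP and 480 with PCN.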

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

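The test of the experiment of the male pools over all calls was set before its result was seen. The tests of read totals, of the splits, of each direction, of male pool 2 and of the unstranded whole-tissue library were chosen only after.

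ncRNA_inter_chr5_4750, at chromosome 5 146879751-146881080, stood out because its TCPOBOP-PCN difference had opposite signs in whole-tissue and nuclear RNA: a log2 difference of -2.0 in the former and 0.75 in the latter. The difference between them was not tested. It rests on 2 and 7 reads with TCPOBOP against 26 and 25 with PCN in whole tissue, and on 0.310 ± 0.121 RPKM (SD, n = 3) against 0.137 RPKM in nuclei. The nuclear values come from 4, 2 and 7 reads in the male pools and 4 reads with PCN. Between the unstranded TCPOBOP and PCN libraries of G81 the log2 ratio was -0.44, the sign of whole tissue. In nuclei agonist and experiment cannot be told apart.

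The 523 calls between female and male pools may reflect sex, experiment or depth. With only 10 splits of the 6 pools no share under 0.05 can be reached: 1 split, the real one, gave 523 calls and the highest of the others gave 0. Lower read totals of the male pools as the whole cause are argued against, since with all libraries thinned to 7.31 M reads at least 44.6% of calls were still called over 20 draws. A first bound of 50%, set with 1 draw known, was dropped because the draws fell on both sides of it (44.6% to 56.0%). The bound of 10% that replaced it was set with these draws known, so meeting it was certain. The argument rests on the calls that remain at equal depth alone, and how much depends on depth stays open. The experiment of the male pools cannot be told apart from sex: both male libraries of experiment G81 lay on the male side for 42.4% of calls and both on the female side for 38.0%, with 64.8% and 18.9% for female-higher and 24.5% and 53.4% for male-higher calls. The 53.4% is what the experiment as the cause of male-higher calls would give, but equal medians moved it to 41.0% and quantile normalization to 36.6%, where 36.2% and 41.0% lay on the male side, so the scaling keeps each direction open, and sex itself stays open.

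The lncRNAs of the chromosome 5 region reached, by their median, 5.25% of the female level in male pool 2 and 0% in pools 1 and 3. Female RNA mixed into that pool is argued against: the chromosome X lncRNA at 100655410-100678927 stood at 0.0489% of its female mean there, against 0.0335% and 0.0327% in the other pools. The reads in the region, counted over overlapping lncRNAs, were 93 in pool 2 against 10 and 0 in pools 1 and 3. Low depth as the cause is argued against for this region, since lower depth gives fewer reads. Pool 2 was the shallowest, at 7.31 M reads against 10.7 M and 11.9 M. The lncRNA at chromosome 5 146227188-146406523, counted once, held 29 reads there against 3 and 0. What remains open is a difference among the 4 pooled livers or mixed reads of overlapping genes, and no biological explanation was tested.

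The unstranded whole-tissue library lay near the nuclear libraries, with r = 0.858 across lncRNAs to the nuclear PCN library and 0.132 to the stranded library of the same treatment. Its compartment label may be wrong, and the test leaves that open. Its difference from the stranded library correlated with that of the nuclear PCN library at 0.829 over intergenic lncRNAs, a value that a shared library protocol could give too. Reads of the opposite strand may contribute, as antisense lncRNAs gained 0.745 more on the log2 scale than intergenic ones, yet intergenic lncRNAs gained 1.87. The unstranded library was also at least 4-fold lower than the stranded one for 171 of 1933 lncRNAs, against 1078 at least 4-fold higher. At chromosome 16 57391224-57391795 the stranded library had 4427 reads, and every unstranded library had 0. Added reads of the opposite strand would not lower a count, and the cause of these losses was not tested. The explanations above cannot be told apart and may not be the only ones, because no stranded nuclear library was analysed here.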

How the results depend on the processing

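The fits to intergenic lncRNAs alone and to thinned libraries, and the pseudocounts in comparisons of single libraries other than the stranded with the unstranded one, were chosen only after the results were seen. For the sex comparison (523 calls) 11 of 20 alternatives stayed within 1.5 times, from 358 to 778 calls. Outside it were 334 with no filter on low values, 239 with a mean RPKM of at least 1, 340 for intergenic lncRNAs alone and 328 with all libraries thinned; the first tests more lncRNAs and the second fewer (1118), and the cause was otherwise not tested. Leaving out each pool gave 205 to 460 calls, 86 to 312 for the nuclear agonist contrast (316) and 415 to 773 for nuclear against whole tissue (764), with fewer libraries in each fit. Pool number as a replicate block gave 287; same-numbered female and male pools correlated at 0.0415, -0.128 and -0.0791, so the number does not pair them, and the lower count is no weaker effect. The additive fit of the 4 stranded libraries already compares agonists within each time and times within each agonist, and the nuclear contrasts have 1 library on a side, which leaves no pairing by pool number.

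The agonist difference in whole tissue had 0 calls in limma in the 4 libraries and under 7 alternatives (162 at an unadjusted p under 0.05). It had 17 with a mean RPKM of at least 1 and 396 in the 12-library fit, and 23 lncRNAs at least 4-fold apart at 3 h and 23 at 6 h. The time difference had 0 (273 unadjusted) in limma, 27 with a mean of at least 1 and 469 in the 12-library fit. The nuclear agonist contrast gave 531 with a pseudocount of 0.01 and 563 without a filter. Agreement between whole-tissue and nuclear differences went from r = 0.162 to 0.314 with a mean of at least 1. A pseudocount of 1 took the antisense median of unstranded over stranded RNA from 2.83 to 0.94 and the count at least 4-fold apart in PCN nuclear against whole-tissue RNA from 1229 to 237, as it shrinks ratios of low values. lncRNAs at least 4-fold apart at both times went from 5 to 11 with a pseudocount of 0.01 and to 1 with a pseudocount of 1. With an estimated correlation the adjusted p of intragenic lncRNAs was 0.161 and of those without a given strand 0.0530. Where not stated, the cause was not tested.

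None of the named lncRNAs changed direction under any alternative. Counted once per named lncRNA and alternative, sex calls were kept in 438 cases and lost in 17. Calls of the nuclear agonist contrast were kept in 111 and lost in 9. Those of nuclear against whole tissue were kept in 118 and lost in 1. In the agonist and time comparisons 9 and 8 such cases gave a call where there was none, and 74 of each gave none. All of the gained calls came from the fits with a mean RPKM of at least 1 or with all 12 libraries. Depth limits lncRNAs under 0.410 RPKM over 1000 bases in the shallowest male pool, the level of 3 reads.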

Other observations

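The tests in this part, of the chromosome X span and of the sign of the agonist difference in nuclei, were chosen only after the results were seen.

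Ranked by mean RPKM over all 12 libraries, 8 of them without strand, the highest entry was ncRNA_inter_chr17_13909, at chromosome 17 39979940-39985776. No entry was matched to a gene by position, so which transcript this entry measures was not checked. It averaged 268 RPKM over the stranded libraries (217 to 292), 336 ± 107 in female nuclear pools (SD, n = 3) and 787 ± 130 in male ones (SD, n = 3), and reached 1834 in the unstranded whole-tissue library. Of the 20 highest by this mean, which weights the unstranded libraries, 8 lay at chromosome 12 between 104966560 and 105651568. An intragenic one there, at 105002287-105133890, stood at 795 ± 49.0 RPKM in female and 1140 ± 169 in male nuclei. Another, at 105585227-105634106, went the other way between protocols, with 708 RPKM in stranded whole tissue against 33.8 ± 10.4 and 3.05 ± 1.09 in female and male nuclei. At chromosome 19 5824552-5845906 an intergenic lncRNA had 14.3 RPKM in stranded and 199 in unstranded whole tissue, 167 ± 16.8 in female and 78.2 ± 20.9 in male nuclei. These loci were chosen after their values were seen.

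The 8 chromosome Y lncRNAs had 0 reads in the female pools (0 of 79.8 M reads, which allows up to 0.0376 per M) and 6 in the male pools, 0.201 per M. The nuclear PCN library held 54 reads (2.46 per M), the unstranded whole-tissue library 29 (0.720 per M) and the 4 stranded libraries 5 together.

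The chromosome X lncRNA at 100655410-100678927 may be Xist, the transcript that coats the inactive X chromosome of females, which is a hypothesis. Its mm9 span of 23518 bases differed by 2.67% from that of Xist (22889 bases), the nearest of 97 lncRNA genes on the minus strand of chromosome X in the GRCm38 annotation. A second gene lay within 5%, at 4.25%, and no sequence or position was compared across builds.

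A second hypothesis is that TCPOBOP-PCN differences at single loci are shared by stranded whole-tissue and unstranded nuclear RNA, which come from separate libraries. Of the 5 lncRNAs at least 4-fold apart at both times in whole tissue, 4 had more than 3 reads in the nuclear libraries, and 4 of 4 (100%) had the same sign there. With 4 lncRNAs the test cannot tell, as chance alone gives this with a probability of 0.0625 if they are independent. They are not, since the overlapping chromosome 19 lncRNAs are among them, so chance gives it more readily. Of 23 at least 2-fold apart, 18 had such reads and 15 of these had the same sign, against 13 of 18 in the unstranded G81 pair, which shares the nuclear PCN library. At least 2-fold in all 4 contrasts were 4 loci higher and 2 lower with TCPOBOP. All PCN libraries come from experiment G81 while the nuclear TCPOBOP pools do not, so an effect of the PCN mice alone may contribute to the 100%.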
